A study of Homo sapiens and Saccharomyces cerevisiae with 9 samples.

How the data were processed

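The series comprised 9 ChIP-exo libraries. In ChIP-exo, chromatin bound by a protein is immunoprecipitated and an exonuclease trims each DNA strand up to the crosslinked protein, so that binding is located at near base-pair resolution. The libraries were grouped by their titles as ERα (2), FoxA1 (2), CTCF (1) and no antibody (1), all from the breast cancer line MCF-7, and mock immunoprecipitation with a non-specific antibody from yeast (3). Per the labels' protocols, MCF-7 cells were grown with 10% serum at 37 °C, kept for 48 h in hormone-stripped serum, treated for 1 h with 17β-estradiol at 100 µM as labelled, and crosslinked in 1% formaldehyde. That concentration is unusually high for estradiol, and whether the labelled unit is right could not be checked here. Yeast cells were grown at 25 °C and crosslinked in the same way. The 2 ERα libraries and the 2 FoxA1 libraries were each made with antibodies from different suppliers, and nothing in the labels says whether they came from separate cultures.

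The values started from were the binding event lists that the authors deposited, 1 per factor and 3 in all, as called by ChExMix, a caller that sorts binding events into subtypes, per the labels. Both libraries of ERα and both of FoxA1 are described with the same list, so the replicates had been merged before deposit. The submitters' processing notes name bcl2fastq 2.16 and 2.20 and BWA 0.7.12, and list hg19 and sacCer3 as genome builds. The version of ChExMix, its use of the control libraries, its filters and its cut-off are not given in the sources used here. No list was used here for the no-antibody or the yeast libraries. Each row of a deposited list holds a position of 1 bp, a score, a subtype name and a strand, without a header. The deposited score was read as the log2 of a p or q value per event, the more negative the more significant. Its finite values reached −1061.42, which is past the natural-log limit of a double-precision number (−744.4) and within the log2 limit (−1074), and its weakest value was −4.322 for ERα, the log2 of 0.05, −4.339 for FoxA1 and −4.345 for CTCF. Whether it is a p or a q value is not given in the sources used here. Minus infinity stood for scores that had underflowed, and these events were ranked first, tied, and taken in list order, which is not strictly by score. The scores are the authors' own values, and were used to describe and rank events within a list. Their levels were not compared between lists, but the scores of paired events of different factors were correlated. Subtype numbers are separate in each list, so Subtype1 of ERα and Subtype1 of CTCF share a number only.

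The following was computed from the lists. Positions are on hg19 and counted from 1. Events of different factors were called shared when their positions lay within 100 bp. The share of events with an event of another factor has a Clopper-Pearson interval at the 95% level. The lists give no read counts, so the depth of each library is unknown and the intervals cover counting error over events only, which are not biological replicates. Because replicates had been merged, no spread between them could be computed for any value. Chance sharing was estimated from 1000 circular shifts of the second list within each chromosome (one-sided permutation test, smallest possible p = 0.001), taking the highest listed position as the chromosome's length, and from 1000 local shifts of 10 to 100 kb. Scores of shared and unshared events were compared by the difference of their medians, with 100000 two-sided permutations of the shared mark within chromosomes (smallest possible p = 1e-05). Each subtype was compared with the rest of its list by a two-sided Fisher's exact test, with Benjamini-Hochberg adjustment over the 14 tests of ERα, the 6 of FoxA1 and the 10 of CTCF. P-values under 1e-300 are given as 1e-300. These tests, the 100 bp distance and their alternatives were fixed before the data were examined.

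Further tests were chosen after seeing the lists. For each pair of subtypes, offsets from −60 to 60 bp along the strand of the first event were scanned for an excess of event pairs over the mean of the offsets within 30 bp, leaving out the nearest 3 bp on each side (one-sided Poisson test, at least 10 pairs, Benjamini-Hochberg adjustment over all offsets of a pair of factors). Pairs within 1 bp of such an offset are called registered. The share of top-ranked events on chromosomes 17 and 20 was compared with that of the remaining events by Fisher's exact test, and the strands of neighbouring CTCF events were compared with 1000 shuffles of the strands.

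The sharing, offset, score and subtype procedures were tested on simulated lists. With 20% of ERα events given a partner in a simulated FoxA1 list, 20.51% were recovered over a background of 0.24%, on 27923 events, and 0 of 20 shifted lists were called. A planted offset of 60 pairs was the sole one called, and 0 were called without one. Shifted lists hold few close pairs, so offsets there could hardly reach the minimum of 10 pairs. False calls of offsets at the density of the real lists were therefore not tested. A planted score difference of −5 was recovered as −4.857, and 0 of 30 subtype tests passed with shuffled subtypes.

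Events were named by rank: for each factor the 5 with the most significant score, and the 10 highest-scoring ERα events that also had a FoxA1 event. All of these had underflowed scores, so list order chose among tied events. A rule fixed before the data were examined also asked for named genes, gene lists, promoter shares and consensus motifs. These were not analysed here, because no hg19 sequence or annotation was used, and the gene table at hand was of another assembly. No gene is therefore assigned to a position. The alternatives were other distances, the more significant events of each list, the 5000 top events of each list, merging of neighbouring events, leaving out chromosomes 17 and 20, which carry segments amplified in MCF-7, and local shifts. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9.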

Results

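Binding of 3 regulators was mapped by ChIP-exo in MCF-7, an estrogen-receptor-positive line of breast cancer epithelial cells, after 1 h of estradiol. ERα is the nuclear receptor that estradiol activates. FoxA1 is a forkhead factor known to open chromatin for ERα, and CTCF is the zinc-finger protein that organises chromatin loops and insulators. The series concerns subtypes of binding events, that is, groups of events of 1 factor that differ in their sequence or in the shape of their ChIP-exo signal. The lists held 27923 ERα events, 30063 FoxA1 events and 65725 CTCF events. Each list merged the libraries of its factor, 2 for ERα, 2 for FoxA1 and 1 for CTCF, so there are no replicate values, and intervals and p-values cover counting over events alone. Read depth is unknown from the lists, and differences in list length cannot be separated from it.

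The FoxA1 and CTCF lists were each dominated by 1 subtype, and the ERα list was not. FoxA1 Subtype2 held 24751 events, 82.3% of the list, while Subtype0 and Subtype1 held 8.86% and 8.80%. CTCF Subtype2 held 45326 events (69.0%), followed by Subtype3 with 14.0%, Subtype4 with 8.40%, Subtype0 with 7.63% and Subtype1 with 1.05% (687 events). Among the 7 ERα subtypes, Subtype1 was the most frequent with 9578 events (34.3%), and Subtype5 held 19.1%, Subtype2 13.4%, Subtype3 10.8%, Subtype0 10.1%, Subtype6 7.18% and Subtype4 5.05%. The main CTCF subtype also carried the most significant scores of its list, with a median of −33.83 against −8.28 in CTCF Subtype1, and the main FoxA1 subtype had a median of −12.02 against −8.08 in FoxA1 Subtype1.

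The first comparison asked how often the receptor and the forkhead factor bound the same places, with CTCF as the unrelated factor in the same cells. ERα and FoxA1 events lay together at 26.4% of ERα events (7377 of 27923; 95% interval 25.9 to 26.9%), against a mean of 0.215% over circular shifts, a 123-fold excess. From the FoxA1 side the share was 24.3%. CTCF was near far fewer ERα events, 3.81% (1065 events; 3.59 to 4.05%), 8.23 times the shifted mean. FoxA1 events lay near a CTCF event in 15.4% of cases (4639 events; 15.0 to 15.8%), 33.5 times the shifted mean. Each of these shares exceeded all 1000 shifts (one-sided permutation p = 0.001, the smallest possible). The CTCF share was 11.6 percentage points higher for FoxA1 than for ERα events (odds ratio 4.60, 95% interval 4.30 to 4.93; Fisher's exact p = 1e-300). Of the ERα events with a FoxA1 event, 4.24% also had a CTCF event, against 3.66% of those without (odds ratio 1.17, Fisher's exact p = 0.028). Neither of these Fisher's tests was among those fixed in advance. The test between FoxA1 and ERα events treats the lists as independent, although their events often lay together. Against local shifts, which keep the crowding of events in the same regions, the excess was 58.3-fold for ERα with FoxA1, 5.38-fold for ERα with CTCF and 24.0-fold for FoxA1 with CTCF. Cutting the lists lowered both the shares and the shifted means. Among events more significant than the median of their lists the shares were 20.6% for ERα with FoxA1 (shifted mean 0.108%), 1.17% for ERα with CTCF (0.234%) and 7.99% for FoxA1 with CTCF (0.233%). Among the 5000 top events of each list they were 15.9% (shifted mean 0.0378%), 0.12% (0.0417%) and 2.36% (0.0444%).

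For ERα with FoxA1 and for FoxA1 with CTCF the excess was steepest at short range. Within 5 bp, 6.63% of ERα events had a FoxA1 event, 557 times the shifted mean, and 2.27% of FoxA1 events had a CTCF event, 89.3 times the shifted mean, whereas 0.183% of ERα events had a CTCF event, a 7.15-fold excess that lay below the 9.15-fold at 20 bp and the 8.23-fold at 100 bp. Within 1000 bp the 3 shares were 40.5%, 24.4% and 13.5%, and the excess had fallen to 20.1-fold, 5.62-fold and 3.08-fold. For these 2 pairings the excess within 5 bp rested largely on fixed offsets, described further below. For ERα with FoxA1, 1852 ERα events had a FoxA1 event within 5 bp. All 8 fixed offsets of these factors lay within 5 bp and held 1619 event pairs. For FoxA1 with CTCF, 514 pairs lay at a single offset of 3 bp, beside 681 FoxA1 events with a CTCF event within 5 bp. The excess without such pairs was not computed.

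**Figure D1:**
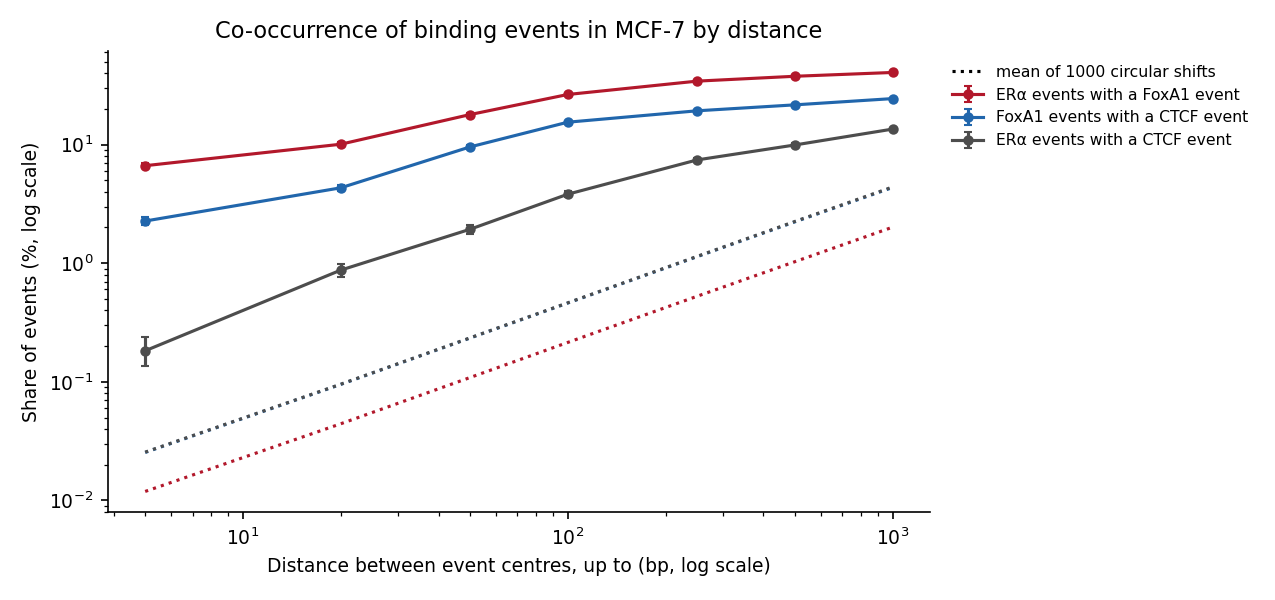
Share of events of 1 factor with an event of another factor (%, log scale) against the largest distance counted (bp, log scale), with 95% Clopper-Pearson intervals; dotted lines are the means of 1000 circular shifts in the colour of each comparison, and those of the 2 comparisons with CTCF coincide. At 100 bp the shares were 26.4% for ERα with FoxA1, 15.4% for FoxA1 with CTCF and 3.81% for ERα with CTCF.

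By the median score of the whole list, events shared by ERα and FoxA1 were the stronger ones in both lists. ERα events with a FoxA1 event had a median score of −22.49, against −13.97 without, a difference of −8.52. FoxA1 events with an ERα event had a median of −16.20 against −10.49, a difference of −5.71 (each permutation p = 1e-05, the smallest possible). Among the most significant 10% of ERα events, 51.2% had a FoxA1 event, and in the weakest 10% the share was 22.5%. CTCF went the other way for FoxA1: FoxA1 events near CTCF were the weaker ones, with a median of −9.26 against −11.71, while the CTCF events near them were the stronger CTCF events, with a median of −44.54 against −25.30 (each permutation p = 1e-05). The CTCF share rose from 11.6% in the most significant 10% of FoxA1 events to 22.6% in the weakest. CTCF events near an ERα event were weak within the CTCF list, with a median of −14.56 against −26.51 (permutation p = 1e-05), and the median scores of ERα events with and without CTCF did not differ detectably (−14.83 against −15.43; permutation p = 0.433). The CTCF share of ERα events was nevertheless uneven along the list, with 4.98% (4.20 to 5.85%) in the most significant 10%, 5.05% (4.27 to 5.93%) in the weakest 10% and 2.90% (2.31 to 3.59%) in portion 4 of 10, a pattern that the medians do not show and that was not tested. The comparisons with CTCF were made after seeing the lists, and all p-values under the threshold also passed Benjamini-Hochberg adjustment over the 6 comparisons.

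**Figure D2:**
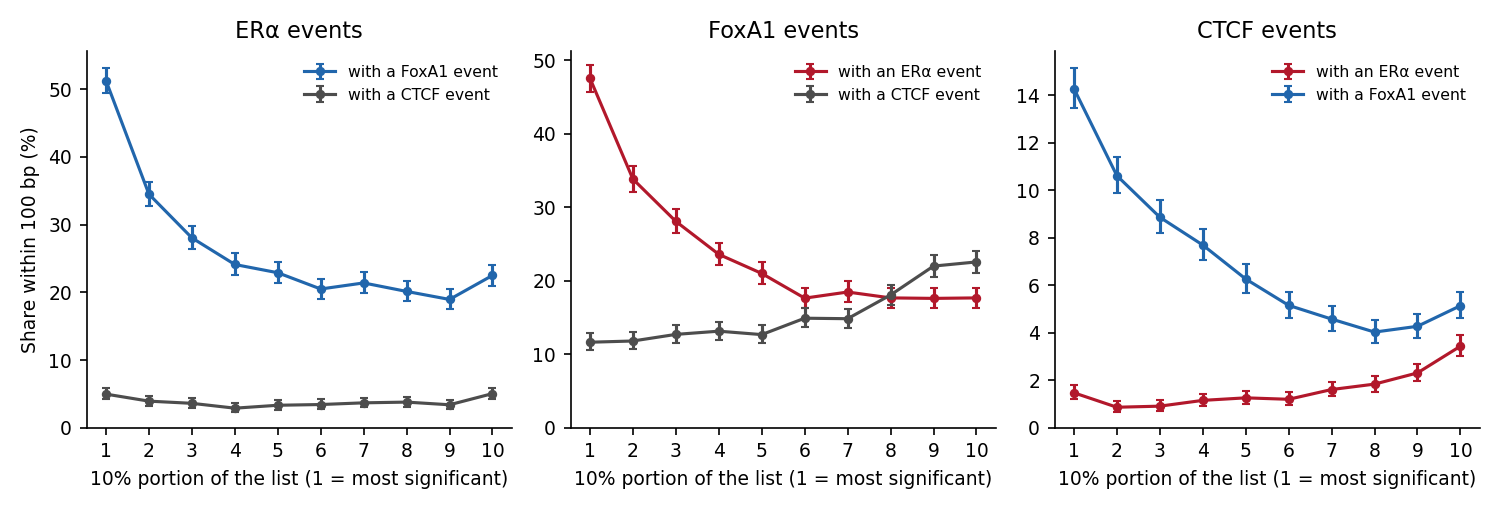
Share of events within 100 bp of an event of another factor (%) in successive 10% portions of the ERα, FoxA1 and CTCF lists, ordered by the authors' score with portion 1 the most significant; bars are 95% Clopper-Pearson intervals. The FoxA1 share of ERα events fell from 51.2% to 22.5%, while the CTCF share of FoxA1 events rose from 11.6% to 22.6%.

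The rate of sharing differed between subtypes, although most shared events belonged to the others: ERα Subtype3 held 1896 of the 7377 ERα events with FoxA1, FoxA1 Subtype0 held 1479 of the 7306 FoxA1 events with ERα, FoxA1 Subtype1 held 977 of the 4639 FoxA1 events with CTCF, and CTCF Subtype1 held 109 of the 1057 CTCF events with ERα and 162 of the 4662 with FoxA1. ERα Subtype3 stood apart from the other ERα subtypes: 63.0% of its 3008 events had a FoxA1 event (61.3 to 64.8%), 41.0 percentage points above the rest of the list (odds ratio 6.05, Fisher's exact test, adjusted p = 1.4e-299). The other 6 ERα subtypes ranged from 16.2% in Subtype4 to 23.6% in Subtype6. Each of these was tested against a rest that held Subtype3, so no difference among the 6 is drawn from those tests. In the FoxA1 list, Subtype0 was the one most often near ERα, at 55.5% of 2665 events (53.6 to 57.4%) against 21.3% (odds ratio 4.62, Fisher's exact test, adjusted p = 4.5e-289), followed by Subtype1 at 28.9% and the main Subtype2 at 20.5%. Both of these often shared subtypes had weak scores for their lists. The median was −12.095 in ERα Subtype3 against −15.43 in the whole ERα list. It was −9.75 in FoxA1 Subtype0 against −11.24 in the whole FoxA1 list. Frequent sharing of a subtype thus did not go with strong scores there. FoxA1 Subtype1 was the one most often near CTCF, at 36.9% of 2647 events (35.1 to 38.8%) against 13.4% (odds ratio 3.79, Fisher's exact test, adjusted p = 7.4e-180), and Subtype0 was the least often so, at 10.5%. Among events beyond the median score the share of FoxA1 Subtype1 near CTCF was 15.8% against 7.53% (odds ratio 2.31). The small CTCF Subtype1 had an ERα event at 15.9% of its 687 events (13.2 to 18.8%) against 1.46% of the rest (odds ratio 12.7, Fisher's exact test, adjusted p = 3.4e-72), and a FoxA1 event at 23.6% (20.5 to 26.9%) against 6.92% (odds ratio 4.15, adjusted p = 5.6e-42). These CTCF Subtype1 events were among the weakest of the list: 32 lay beyond its median score, and 0 of these 32 had an ERα or a FoxA1 event among the more significant events of those lists, which allows a share of up to 10.9% (upper 95% limit). CTCF proximity ranged from 3.36% in ERα Subtype1 (lower than the rest, Fisher's exact test, adjusted p = 0.0073) to 5.04% in ERα Subtype4 (higher, adjusted p = 0.028). Both calls were lost among events beyond the median score (Fisher's exact test, adjusted p = 0.542 and 0.0524). There the odds ratio of ERα Subtype1 was 0.882 (0.637 to 1.22) over 5195 events, against 0.824 (0.721 to 0.942) over 9578 in the whole list. That of ERα Subtype4 was 1.88 (1.10 to 3.21) over 721 events, against 1.36 (1.06 to 1.74) over 1410. The call of Subtype4 was also lost at 50 and 500 bp (Fisher's exact test, adjusted p = 0.189 and 0.252). Of the 30 subtype tests, 19 passed an adjusted p of 0.05, those of the other 6 ERα subtypes with FoxA1 included.

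**Figure D3:**
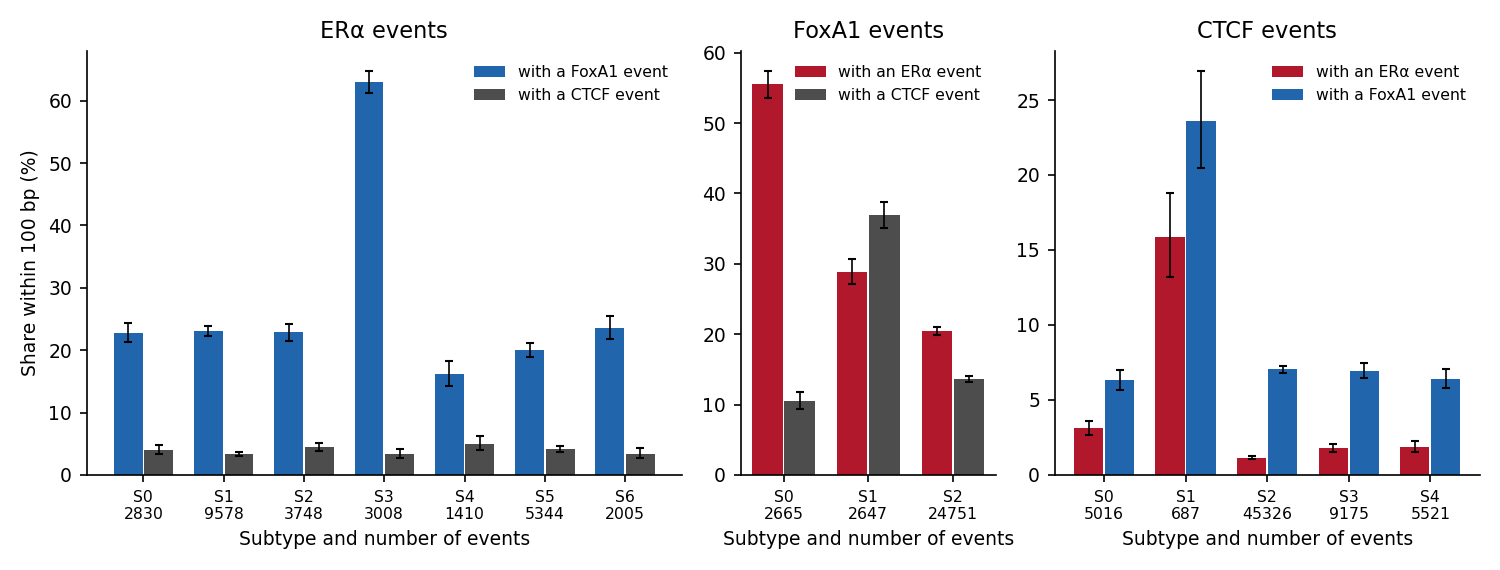
Share of each subtype's events within 100 bp of an event of another factor (%), for the ERα, FoxA1 and CTCF lists; the number under each subtype (S0 to S6) is its event count, bars start at 0 and error bars are 95% Clopper-Pearson intervals. ERα Subtype3 (63.0% with FoxA1), FoxA1 Subtype0 (55.5% with ERα), FoxA1 Subtype1 (36.9% with CTCF) and CTCF Subtype1 (15.9% with ERα and 23.6% with FoxA1) stand above the other subtypes of their lists.

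Part of the close sharing fell at fixed offsets in base pairs, in an analysis chosen after the lists were seen. Of the event pairs within 60 bp, 1619 of 5638 lay at such an offset for ERα with FoxA1. The numbers were 708 of 3344 for FoxA1 with CTCF and 11 of 653 for ERα with CTCF. Most pairs within 60 bp thus lay outside these offsets, but most of those within 5 bp for ERα with FoxA1 lay at them. ERα Subtype3 and FoxA1 Subtype2 events lay on opposite strands with an offset of −1 bp in 984 cases, against a mean of 2.30 pairs at neighbouring offsets. Such registered pairs included 987 ERα Subtype3 events, 32.8% of the subtype (31.1 to 34.5%), and made up 68.2% of all its pairs with FoxA1 Subtype2 within 60 bp. FoxA1 Subtype1 and CTCF Subtype2 lay on the same strand with an offset of 3 bp in 514 cases, against a neighbouring mean of 0.481, and 515 registered pairs took in 19.5% of FoxA1 Subtype1 (18.0 to 21.0%). FoxA1 Subtype0 was registered with ERα Subtype1 on the same strand at 1 bp in 262 cases, and with ERα Subtype5 on the opposite strand at −2 bp in 244 cases, 9.83% and 9.16% of FoxA1 Subtype0. Each of these 4 offsets had a Poisson adjusted p of 1e-300. The test shows an excess over neighbouring offsets and not its source. How the caller placed positions and strands is not given in the sources used here. Placement by the caller was therefore not separated from the spacing of the bound proteins. FoxA1 Subtype0 also had smaller registers with ERα Subtype2 (33 pairs, opposite strands, 2 bp), with ERα Subtype1 on opposite strands (17 pairs, 3 bp) and with ERα Subtype0 (10 pairs, opposite strands, −5 bp). Nor was FoxA1 Subtype1 in register with CTCF Subtype2 alone. It also had registers with CTCF Subtype3 (40 pairs, same strand, 7 bp), Subtype0 (30 pairs, opposite strands, 2 bp) and Subtype4 (23 pairs, opposite strands, 0 bp). FoxA1 Subtype2 had further registers with ERα Subtype1 (57 pairs, same strand, −1 bp) and ERα Subtype2 (12 pairs, opposite strands, 4 bp). With CTCF Subtype2 it had 27 pairs on opposite strands at 5 bp, and 24 and 20 on the same strand at −31 and −29 bp. With CTCF Subtype3 it had 10 pairs (opposite strands, 2 bp). FoxA1 Subtype0 had 20 pairs with CTCF Subtype2 (opposite strands, −7 bp). Over all subtype pairs, 8 offsets passed for ERα with FoxA1, 9 for FoxA1 with CTCF and 1 for ERα with CTCF, the last with 11 pairs (ERα Subtype1 with CTCF Subtype2, opposite strands, −6 bp). Among the more significant events of both lists the registered pairs of the 4 largest registers numbered 371, 79, 107 and 86, in the order given.

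The median scores of registered events are set beside those of the other events of their subtype, without a test. FoxA1 Subtype2 events in register with ERα Subtype3 had a median of −27.76, against −11.71 for other events of Subtype2, while the ERα Subtype3 events themselves had −13.41 against −11.65. CTCF Subtype2 events in register with FoxA1 Subtype1 had a median of −71.13 against −33.31, and their FoxA1 partners had −6.69 against −8.63. ERα Subtype1 events in register with FoxA1 Subtype0 had a median of −80.49 against −17.19, and their FoxA1 partners had −11.07 against −9.54. For ERα Subtype5 events in register with FoxA1 Subtype0 the medians were −38.6 against −15.43, and for their FoxA1 partners −10.00 against −9.65. Carry-over of reads between libraries was not tested for these registers of FoxA1 Subtype0. The highest-scoring ERα Subtype3 event of the first pairing was at chromosome 20, position 52402807 (plus strand, score −950.28), with its FoxA1 partner at 52402806 (minus strand, −419.88). The next was at chromosome 5, position 66531684, where the ERα score was −602.08 and the FoxA1 score −9.02. The FoxA1 Subtype1 event at chromosome 20, position 52486517 (score −148.70), lay 3 bp from the CTCF event at 52486520, whose score had underflowed.

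**Figure D4:**
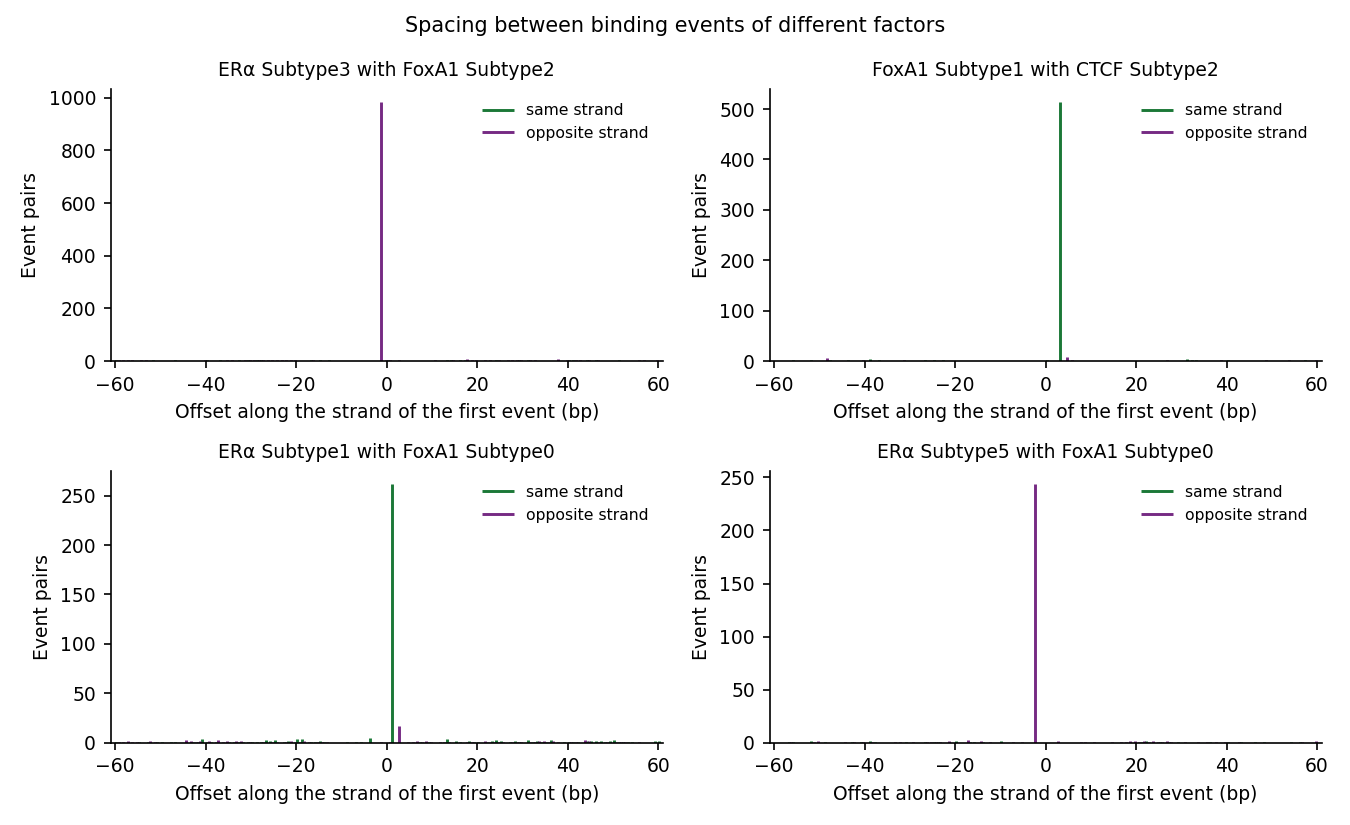
Number of event pairs at each offset (bp, along the strand of the first event) within 60 bp, for the 4 subtype pairings with the most registered pairs; green lines are pairs on the same strand and purple lines pairs on opposite strands, drawn slightly apart. The pairs pile up at 1 offset in each panel, with 984 pairs at −1 bp, 514 at 3 bp, 262 at 1 bp and 244 at −2 bp.

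The most significant events of all 3 factors were over-represented on chromosomes 17 and 20, although most of them lay elsewhere. Of the top 1% of events, 21.5% of ERα (60 of 279; 16.8 to 26.8%), 36.7% of FoxA1 (110 of 300; 31.2 to 42.4%) and 47.9% of CTCF events (315 of 657; 44.1 to 51.8%) lay on these chromosomes, which held 9.52%, 9.26% and 7.90% of all events. The odds ratios were 2.64 for ERα (1.98 to 3.52), 5.86 for FoxA1 (4.62 to 7.44) and 11.4 for CTCF (9.72 to 13.3), with Fisher's exact p of 1.7e-09, 1.3e-38 and 2.8e-167. The odds ratios were smaller with a wider choice of top events, 1.55, 2.37 and 3.47 for the top 5% and 1.33, 1.70 and 2.30 for the top 10%. This comparison too was chosen after the lists were seen, and other chromosomes were not compared in this way. The region from 52 to 53 Mb of chromosome 20 held 11 of the top ERα events, 24 of FoxA1 and 17 of CTCF. Regions of other chromosomes were also among the 10 with most top events. From 64 to 65 Mb of chromosome 3 there were 14 of CTCF, from 128 to 129 Mb of chromosome 9 there were 5 of FoxA1, and from 85 to 86 Mb of chromosome 16 there were 4 of ERα.

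Scores had underflowed for 53 ERα, 7 FoxA1 and 18 CTCF events, which are tied at the top of their lists. The first 5 of each are named here in list order, which is not strictly by score, so they are examples and do not show where the strongest events lie. For ERα they were on chromosome 20, at positions 52812054 (Subtype5, plus strand), 52743865 (Subtype5, minus), 52740264 (Subtype1, plus), 46704850 (Subtype1, minus) and 52740431 (Subtype1, plus). For FoxA1 they were of Subtype2 on the minus strand, at 59646092, 59646115 and 59434204 on chromosome 17 and at 52740474 and 55839369 on chromosome 20. For CTCF they were of Subtype2, at 52532475, 52486520 and 52556623 on chromosome 20, 59489908 on chromosome 17 and 64009233 on chromosome 3. The first 10 of the tied ERα events with a FoxA1 event within 100 bp lay on chromosome 20, from 2 to 55 bp from it, but other tied ERα events lay 1 bp from a FoxA1 event at position 69330229 of chromosome 11 and at 116828390 of chromosome 12. The nearest of the 10 were the ERα events at 52812054 and 52743865, each 2 bp from a FoxA1 event and each in the register of ERα Subtype5 with FoxA1 Subtype0. Position 52740431 was listed more than once for ERα and appeared at ranks 4 and 7 of these 10.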

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

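The test that sets ERα against FoxA1 at CTCF sites was chosen after the result was seen, while the other tests in this part had their bounds set before their results were seen.

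FoxA1 events lay within 100 bp of a CTCF event 11.6 percentage points more often than ERα events did, 15.4% against 3.81% (odds ratio 4.60), a difference between factors assayed in the same cells under the same treatment. Outside FoxA1 Subtype1 the CTCF share of FoxA1 events was still 13.4%. The lists were called separately, and the effect of read depth on the difference was not tested. FoxA1 events near CTCF were weak within their list. Among events more significant than the median of their list the shares were 7.99% and 1.17%, both lower in part because fewer CTCF events were then counted.

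Within this excess, 515 FoxA1 Subtype1 events lay in register with CTCF Subtype2 events, and fewer lay in register with CTCF Subtype3, Subtype0 and Subtype4 events. Signal at strong CTCF sites in any immunoprecipitation would give ERα events at the same sites. Of 45326 CTCF Subtype2 events, 16 had an ERα event within 5 bp, against 573 with a FoxA1 event, a ratio of 0.0279. ERα events were thus rare at these sites. The 573 include the registered events that prompted the test, the count was not limited to strong sites, and the ERα read depth is unknown. The ratio therefore does not decide the question. Carry-over of reads from the CTCF library into the FoxA1 libraries could give FoxA1 events in register at the strongest CTCF sites. It would put registered FoxA1 events at most of the 100 highest-scoring CTCF Subtype2 events, and 17% had one (10.2 to 25.8%), below the 50% set for carry-over and not below the 10% set against it. The scores of the registered pairs outside chromosomes 17 and 20 had a Spearman rho of 0.0522 across 442 event pairs (bootstrap interval −0.0334 to 0.144; permutation p = 0.275; Pearson r −0.0055). This is under the 0.5 set for carry-over, but the interval reaches past the 0.1 set against it. Over all registered pairs the FoxA1 median score was −6.69, near the weakest listed FoxA1 score of −4.339. So narrow a range can hold rho down, so missing the 0.5 says little against carry-over. Carry-over and binding of FoxA1 at CTCF sites, which was not tested, therefore cannot be told apart.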

How the results depend on the processing

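The alternatives for registered pairs and for chromosomes 17 and 20 were chosen after the data were seen. The shares of ERα events with FoxA1, ERα with CTCF and FoxA1 with CTCF exceeded the shifts under all 10 alternatives each, ranging from 10.1 to 40.5%, from 0.12% (permutation p = 0.026, top 5000 events) to 13.5%, and from 2.36 to 24.4%. The score differences kept their sign and call, from −9.09 to −7.79 for ERα and from −5.71 to −5.41 for FoxA1. Of the 30 subtype tests, 19 passed at 100 and at 50 bp, 25 at 500 bp and 15 among events beyond the median score. Keeping those events alone changed, by construction, the event numbers to 13961 for ERα, 15031 for FoxA1 and 32862 for CTCF. It also left 371 registered pairs of ERα Subtype3 with FoxA1 Subtype2, 79 of FoxA1 Subtype1 with CTCF Subtype2, and 107 and 86 of ERα Subtype1 and Subtype5 with FoxA1 Subtype0. It turned the difference of CTCF Subtype1 from the rest to −0.49 percentage points for ERα and −3.68 for FoxA1, with 32 events left and no call (adjusted p of 1 and 0.789). At 500 bp the differences turned to 0.091 for ERα Subtype6 with FoxA1, which lost its call (Fisher's exact test, adjusted p = 0.943), and to 2.00 for ERα Subtype6 with CTCF and 2.71 for CTCF Subtype0 with FoxA1, which gained one (adjusted p = 0.0065 and 4.4e-09). Without a call before or after, CTCF Subtype3 with FoxA1 turned to 0.324 at 500 bp and to 0.662 beyond the median score, and CTCF Subtype0 with FoxA1 to 0.414 beyond the median score. The cause was not tested. The share of top events on chromosomes 17 and 20 kept its direction and call but fell from the top 1% to the top 10%, to 11.96% for ERα, 13.97% for FoxA1 and 14.97% for CTCF. Of the other results on subtypes and reciprocal shares, 84 values kept direction and call, 9 gained a call and 6 lost one without a change of sign.

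No paired analysis was possible because each factor has 1 merged list, and for the same reason leaving out a replicate was not possible. The alternatives for motif, promoter and gene list shares were not run, since no hg19 sequence or annotation was used here. Read depth, unknown here, limits which weak events were listed, and so the shares in the weakest part of each list.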

Other observations

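The analyses of neighbouring CTCF events and the test of ERα and FoxA1 activity on chromosomes 17 and 20 were chosen after the data were seen, while the tests of carry-over and of DNA copies had their bounds set before their results were seen.

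Neighbouring CTCF Subtype2 events did not take their strands independently, and the arrangement depended on the gap between them. Among 8563 neighbours over 100000 bp apart, 31.9% were minus then plus in chromosome order (30.9 to 32.9%) and 20.6% plus then minus (19.7 to 21.4%), against 25.0% for each after shuffling the strands (permutation p = 0.002, the smallest possible two-sided, adjusted p = 0.0028 for each). Among 10553 neighbours 5000 to 20000 bp apart the order was the other way, with 27.9% plus then minus and 20.2% minus then plus (permutation test, adjusted p = 0.0028 for each). Between 20000 and 100000 bp, 24.8% were plus then minus (permutation test, adjusted p = 0.426) and 25.8% minus then plus, the latter above the shuffled 25.0% (permutation test, adjusted p = 0.0028). Of 373 neighbours within 200 bp, 66.5% were on the same strand (61.4 to 71.3%), against 49.9% after shuffling (permutation test, adjusted p = 0.0028). CTCF motif orientation is known to matter for chromatin loops, but how the listed strand relates to the direction of the motif was not determined here. With the events of all CTCF subtypes the shares over 100000 bp were 29.9% and 21.4%.

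ERα Subtype3 events in register with FoxA1 Subtype2 raise the question whether ERα signal of this subtype comes from FoxA1-bound sequence. Carry-over of reads from the FoxA1 libraries into the ERα libraries could produce it, as could ERα held at the site through FoxA1, which was not tested. Of the 100 highest-scoring FoxA1 Subtype2 events, 20% had a registered ERα Subtype3 event (12.7 to 29.2%), below the 50% set for carry-over and not below the 10% set against it. Over 899 registered pairs outside chromosomes 17 and 20 the scores had a Spearman rho of 0.178 (bootstrap interval 0.114 to 0.239; permutation p = 0.0001, the smallest possible; Pearson r 0.163), between the 0.1 and 0.5 set in advance. These correlations are across events, which are not independent replicates, and carry-over cannot be told apart from shared binding on them.

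For the gathering of top events on chromosomes 17 and 20, a concentration of ERα and FoxA1 activity would by itself leave CTCF without it. Yet CTCF had an odds ratio of 11.4 (9.72 to 13.3), above the 2.64 of ERα. Such activity alone therefore does not account for the gathering of CTCF events. The odds ratios, known when the test was chosen, cannot exclude that it adds to the gathering of ERα and FoxA1 events. A candidate explanation is more DNA copies of segments amplified in MCF-7, since chromosomes 17 and 20 are known to carry such segments and extra copies add reads for every factor. Of the 10 bins of 1 Mb with most top CTCF events, 4 were among the 10 of ERα, between the 5 set for this explanation and the 1 set against it, while FoxA1 and CTCF shared 5 of 10, which reaches the upper bound set for ERα. This explanation stays open, and ERα bins with as few as 3 top events limit the test. Bins with equal numbers of top events were ordered by chromosome name, so the count of shared bins may depend on that order. The number of bins shared by chance was not estimated. Both FoxA1 and ERα shared the region from 52 to 53 Mb of chromosome 20 with CTCF. The share of ERα events with a FoxA1 event without these chromosomes was 26.4%, so co-occurrence did not rest on them.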
